A study of Gallus gallus with 2 samples.

How the data were processed

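Granulosa layers of chicken (Gallus gallus) hierarchical (HF) and prehierarchical (PHF) follicles were dissociated with collagenase and loaded on a 10x Chromium controller with the 3' v3 chemistry, per the labels' protocols, and read on a BGI T7 sequencer. The samples were 1 HF and 1 PHF library. How many birds and follicles went into each is not given in the sources used here. The deposited files hold whole-number counts of UMIs per gene and barcode, not normalized. Cell Ranger 7.0.1 and the assembly GRCg7b are named in the submitters' processing notes. Whether reads in introns were counted is not given in the sources used here. Of 25466 features, 25216 carried a gene symbol of the RefSeq annotation of GRCg7b, from which coordinates were taken; mitochondrial genes were matched by locus tag. Reads shared between near-identical gene copies were not examined here.

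Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, and when not called a doublet by Scrublet in scanpy 1.11.5, run on each library alone with its automatic threshold and an expected rate of 0.8% per 1000 barcodes. Scrublet called 533 HF barcodes (3.50%) and 785 PHF barcodes (6.16%). The mitochondrial limit was exceeded by 2913 HF (19.1%) and 1371 PHF barcodes (10.8%). This left 11286 HF cells (74.1%) and 10512 PHF cells (82.5%), with medians of 10072.5 and 8141.5 UMIs.

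Cells of both libraries were clustered together without integration: counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used, with Leiden clustering at resolution 0.8. A cluster was called granulosa-like unless more of its 10 leading genes were markers of another class than of granulosa cells, fewer than 3 granulosa markers were detected, or its median UMI count was under 1/3 of that of its library with no granulosa marker leading. Leading genes were those with the highest CPM ratio to the other cells of the same library, at 100 CPM or more. This own-library basis was decided after the clusters were seen and before HF and PHF were compared; the other basis, against both libraries, is given as an added alternative. Marker lists covered granulosa, theca interna, theca externa or fibroblast, smooth muscle or pericyte, endothelial, myeloid, lymphocyte, erythroid, thrombocyte, germ and surface epithelium classes. STAR and CYP11A1 are also made by theca interna cells.

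UMIs of granulosa-like cells were summed per library. CPM was given with an exact Poisson interval and the log2 ratio of HF over PHF with an exact conditional binomial interval. A gene with 0 counts in a library was set at 3 counts there as a bound. Cells are not replicates, so no p-value was computed, and genes were counted by size: at least 2-fold apart with at least 50 CPM in the higher library. Because each library is 1 sample, these counts describe the 2 libraries, not the follicle stages. For 19 gene lists the median log2 ratio of members with at least 10 CPM in either library was placed among 10000 random lists of the same size matched on expression in 20 bins. List members were counted as higher at 1.5-fold or more. Listed symbols absent from the files were matched through RefSeq synonyms where these pointed to 1 feature. ZPD was matched to UMOD, KRT19 to KRT24, ALAS2 to ALAS1 and CCNB2 to CCNB1 in this way, among others. Whether the genes of such a pair are the same was not checked. TMM factors came from edgeR 4.0.16 in R 4.3.3, used for scaling only.

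The genes named are the 12 highest and 12 lowest log2 ratios among genes with a symbol and at least 50 CPM in the higher library, the 15 key genes, up to 4 members with the largest absolute ratio per list (a few members under this rule are left out of the text), and 5 leading genes per cluster. CYP17A1, COL1A1, HBA1 and PTPRC were named as markers after their values were seen. For shares of cells with a UMI, each cell was thinned at random to 3000 UMIs, and shallower cells were left out. Granulosa-like cells of each library were also clustered alone at Leiden resolution 0.5, and cluster sizes were not compared between libraries.

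Groups, lists, thresholds, named gene rules and most alternatives were fixed before the data were examined. The alternatives were mitochondrial limits of 10% or none, at least 1000 genes, doublets kept, all kept cells, Leiden resolutions 0.4 and 1.2, median of ratios and TMM scaling, 20 CPM or only 10 UMIs as gene filter, a 50 CPM filter for lists, the mean of CPM per cell, thinning to 1500 UMIs and a score threshold of 5 UMIs. The alternatives added after seeing the data were the other basis for leading genes and a ribosomal list without S6 kinases and RPS19BP1. While the ribosomal list was being coded these genes had been left out; the rule fixed beforehand takes them in, and it is the one reported as the main value. A list median was counted as moved where it left the interval obtained by resampling the list's members 2000 times.

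The ratio step was tested on simulated data for HF over PHF with 25466 genes, 200 of them changed. It called 50 of 50 genes changed 2.5-fold, 50 of 50 changed 4-fold, 50 of 50 changed 16-fold, 0 of 50 changed 1.5-fold and 0 of 17694 unchanged genes with at least 10 UMIs. The interval held the true value for 95.5% of unchanged genes and for 90% to 98% of changed genes by fold. The counts were drawn with Poisson error alone, as the interval assumes, so variation between birds, libraries or cells was not tested. The list step, run on 9053 genes, placed 6% of 100 unchanged lists of 20 genes outside percentiles 2.5 to 97.5, and it placed 100% of lists shifted by 2 on the log2 scale above percentile 97.5. Members of these simulated lists varied independently of each other, and smaller shifts were not tried. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9 and matplotlib 3.10.9.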

Results

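Single-cell RNA sequencing was done on the granulosa layer of chicken ovarian follicles. Granulosa cells line the inside of the follicle wall, around the yolk-filled oocyte. One library came from hierarchical follicles (HF), the large yolky follicles ranked for ovulation, and 1 came from prehierarchical follicles (PHF), the smaller ones not yet in that ranking. The series was made to describe the variety of granulosa cells and how they differ with follicle development. The HF library held 15228 barcodes and 134423329 UMIs, with a median of 8975.5 UMIs and 2860 genes per barcode. The PHF library held 12744 barcodes and 101324985 UMIs, with medians of 7793 UMIs and 3185 genes. Mitochondrial transcripts took a median of 12.99% of UMIs per HF barcode and 9.70% per PHF barcode. There was 1 library per group, so no difference below has a replicate check, and no test was made. All intervals are 95% intervals for counting error only.

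Nearly all cells of both libraries carried granulosa genes. After filtering, 11286 HF and 10512 PHF cells remained, and they fell into 21 clusters when clustered together. Clusters were almost complete splits by library. Cluster 11, of dividing cells, was the exception with 36 HF and 180 PHF cells. Clusters called granulosa-like held 9896 HF cells, or 87.7% (87.1% to 88.3%, Clopper-Pearson), and 9427 PHF cells, or 89.7% (89.1% to 90.3%). The HF cells of this class were in clusters 0, 1, 2, 3, 4 and 6, and the PHF cells in clusters 11, 12, 14, 15, 16, 18, 19 and 20, apart from a few cells, so the class was held by different clusters in each library. The clusters left without a name held 12.3% of HF and 10.3% of PHF cells. The PHF share of granulosa-like cells was 65.5% when leading genes of a cluster were taken against both libraries, a choice added after seeing the data, and 75.1% to 80.1% with 3 of the other settings.

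Most markers of other cell types were low, with some exceptions. CYP17A1, the theca enzyme that makes androgens, was at 0.244 CPM in HF and 0.661 CPM in PHF, where CPM is the UMI count of a gene scaled by the total UMIs of the library. The collagen gene COL1A1 was at 0.878 and 0.190 CPM, and the blood globin HBA1 at 0.8001 and 0.325 CPM. The leukocyte gene PTPRC was at 2.29 and 8.84 CPM. Among the exceptions, the erythroid gene HEMGN was at 222 CPM in HF and 445 CPM in PHF, the collagen gene COL1A2 at 60.6 and 68.6 CPM, the myeloid gene CD74 at 56.9 and 10.7 CPM, and the endothelial gene EGFL7 at 37.3 and 61.9 CPM. In PHF the matrix gene POSTN was at 126 CPM, the endothelial gene EMCN at 97.2 CPM and the epithelial gene EPCAM at 73.1 CPM. The marker medians in HF and PHF were 0.770 and 14.1 CPM for theca interna, 0.130 and 0.751 CPM for theca externa or fibroblasts, 0.426 and 3.92 CPM for smooth muscle or pericytes, and 0.8001 and 2.21 CPM for endothelium. They were 0.0783 and 0.370 CPM for myeloid cells, 0.165 and 0.986 CPM for lymphocytes, 0.0957 and 0.162 CPM for erythroid cells, and 0.252 and 1.21 CPM for thrombocytes. They were 0.0261 and 0.868 CPM for germ cells and 0.287 and 1.42 CPM for surface epithelium. The theca interna median in PHF rested on 4 measured markers, among them HSD17B1, which PHF granulosa-like cells also expressed. No class that lacks granulosa genes was recovered, so the background of free RNA for these genes could not be read from another cell type.

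Granulosa-like cells of the HF and PHF libraries differed widely. Of 4387 genes with at least 50 CPM in either library, 411 were at least 2-fold higher in HF, 1139 were at least 2-fold higher in PHF and 2837 lay between. At least 10-fold differences were found for 61 genes higher in HF and 145 higher in PHF. The sums behind these ratios held 104650957 HF UMIs (median 10399.5 per cell) and 80531866 PHF UMIs (median 8230). The 10 most abundant genes held 17.7% of the HF UMIs and 11.005% of the PHF UMIs. The split depended on scaling. TMM scaling, which sets the typical gene at no difference, raised every log2 ratio of HF over PHF by 0.67, and it gave 902 genes higher in HF and 400 higher in PHF. The median log2 ratio of the 4387 genes was -0.52 by CPM. Ratios below are by CPM, and the TMM value is given where the direction of a median or key gene differs.

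Genes at the HF end of the comparison included the receptor of luteinizing hormone. LHCGR (chromosome 3, 7804404 to 7823960, GRCg7b) was at 581 CPM (577 to 586) in HF and 4.84 CPM (4.37 to 5.35) in PHF, 120-fold higher. GRK5, a kinase that desensitizes G protein-coupled receptors, was 71.5-fold higher. CRACD was highest by ratio, at 469 against 1.34 CPM (350-fold). CRIP1 followed at 329-fold and TRIM14 at 287-fold. HSD11B2, which inactivates glucocorticoids, was 174-fold higher and the cytochrome P450 gene CYP1B1 was 151-fold higher. PCP4, KIAA0040, SYBU, DYNC1I1 and HTRA1 completed the 12 highest, at 143-, 119-, 106-, 88.8- and 63.1-fold. The log2 ratio of SYBU, 6.72, was 4.66 over all kept cells.

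Genes at the PHF end included secreted regulators of early follicles. AMH (chromosome 28, 2443983 to 2449342), a hormone of growing follicles, was at 206 CPM (203 to 209) in PHF and 0.478 CPM (0.355 to 0.630) in HF, 431-fold higher in PHF. FST, the follistatin that binds activins (chromosome Z, 16612271 to 16618886), was at 913 CPM (907 to 920) in PHF and 5.23 CPM (4.80 to 5.68) in HF. The steroid 5-beta-reductase AKR1D1 was 1515-fold higher in PHF, from 6 HF and 6994 PHF UMIs. LECT1, TH (tyrosine hydroxylase) and MMEL1 were 934-, 196- and 160-fold higher. DLGAP1 was 135-fold and SMAD7, an inhibitor of TGF-beta signalling, 127-fold higher. Within HF, SMAD7 was at 54.5 and 571 CPM in HF clusters 3 and 8 (886 and 68 cells, described below) and at most 1.29 CPM in the other clusters. The ligand WNT6 was 109-fold, EMCN 97.0-fold, HSD17B1 76.7-fold and CHSY3 70.2-fold higher in PHF.

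**Figure D1:**
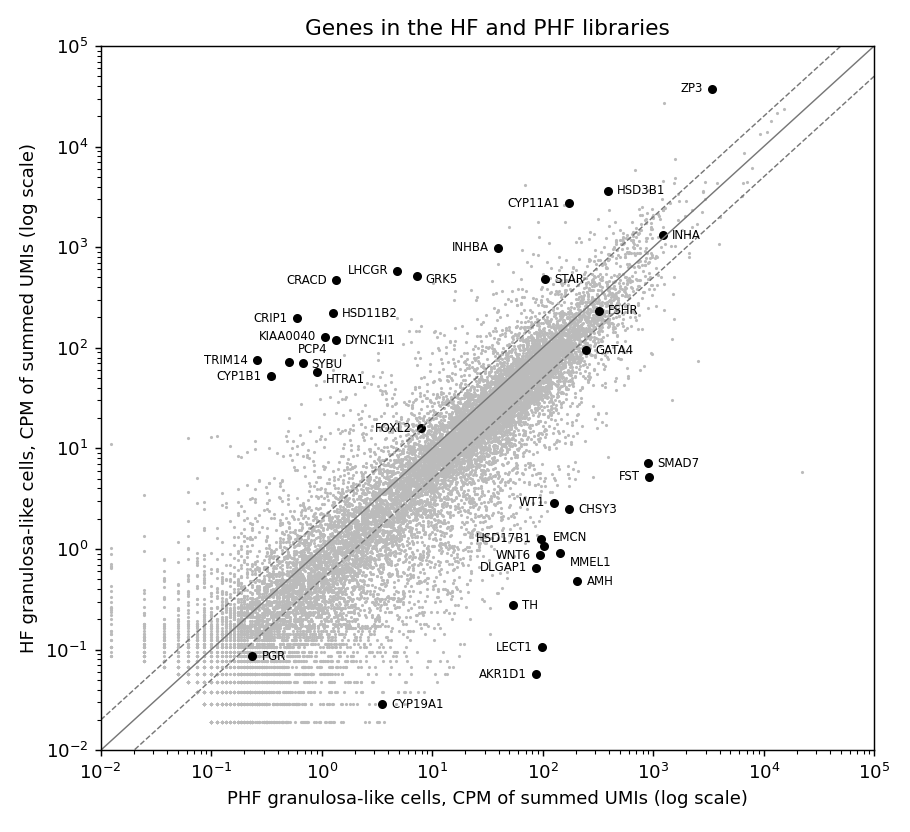
Each point is 1 gene in granulosa-like cells, with its CPM of summed UMIs in PHF on the horizontal and in HF on the vertical axis, both on log scales; the solid line marks equal values and the dashed lines 2-fold differences. Black points name the 12 highest and 12 lowest ratios and the key genes. LHCGR lies 120-fold above the line of equal values and AMH 431-fold below it.

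Genes for making progesterone from cholesterol were higher in HF as a group. Of 9 measured genes of steroidogenesis, 5 were at least 1.5-fold higher in HF, 1 was higher in PHF and 3 lay between, with a median log2 ratio of 1.26. By TMM 8 were higher in HF and 1 in PHF. The median by CPM was at percentile 99.95 among random lists matched on expression. CYP11A1, which cleaves the cholesterol side chain (chromosome 10, 2586264 to 2590520), was at 2734 CPM (2724 to 2745) in HF and 174 CPM (171 to 176) in PHF, 15.8-fold. The PHF mean of CYP11A1 joined unlike cells, at 479 CPM in PHF clusters 2 and 6 (described below) and 61.0 CPM in the other PHF cells. HSD3B1, which forms progesterone, was at 3632 and 387 CPM, 9.38-fold. STAR, which carries cholesterol into mitochondria (chromosome 22, 2436633 to 2439887), was at 480 and 106 CPM, 4.54-fold. In PHF clusters 2 and 6 STAR was at 277 CPM, against 42.7 CPM in the other PHF cells. HSD17B1, which forms estradiol from estrone, went the other way, at 1.26 CPM in HF and 96.7 CPM in PHF. The aromatase CYP19A1 had 3 UMIs in HF and 284 in PHF, a log2 ratio of -6.94 (-9.23 to -5.38).

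Cholesterol genes and the egg coat genes were also higher in HF. Of 20 genes of cholesterol synthesis and uptake, 17 were at least 1.5-fold higher in HF, 0 were higher in PHF and 3 lay between (median log2 ratio 2.28, percentile 100). HMGCS1, at the start of the pathway, was at 947 and 65.6 CPM (14.4-fold). DHCR7 and FDPS were 13.7-fold and 12.6-fold higher. Of the zona pellucida list, 2 genes were measured and both were higher in HF (median 3.77, percentile 99.94). ZP3, a protein of the inner perivitelline layer around the oocyte, was at 37460 and 3395 CPM (11.03-fold) and took 3.75% of HF UMIs against 0.339% in PHF. UMOD, matched to the listed ZPD through a RefSeq synonym, was at 2618 and 156 CPM. Among 18 genes of lipid transport and storage, 3 were higher in HF, 11 were higher in PHF and 4 lay between (median -0.82, percentile 19.5), but by TMM 5 were higher in HF and 6 in PHF (median -0.15). NPC2, which moves cholesterol out of lysosomes, was at 27265 CPM in HF and 1259 CPM in PHF, while the fatty acid binding genes FABP7, FABP5 and FABP4 were 41.3-, 33.8- and 24.2-fold higher in PHF. Within PHF, FABP5 was at 512 CPM in PHF clusters 2 and 6 (described below) and 48.7 CPM in the other cells. FABP4 was at 150 and 11.6 CPM in these.

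Hormone and growth factor signalling genes were divided between the libraries. For gonadotropin and ovulatory signalling, 4 of 13 genes were higher in HF, 6 were higher in PHF and 3 lay between (median -0.46, or 0.20 by TMM with 5 higher in HF and 4 in PHF, percentile 42.8). The cyclic AMP phosphodiesterase PDE4D was 19.8-fold higher in HF, and CEBPB and ADAMTS1 were 13.4- and 11.4-fold higher in PHF. FSHR, the receptor of follicle-stimulating hormone, was at 234 CPM (231 to 237) in HF and 323 CPM (319 to 327) in PHF, a log2 ratio of -0.46 by CPM and 0.20 by TMM. PGR, the progesterone receptor, had 9 UMIs in HF and 19 in PHF. For the TGF-beta superfamily, 8 of 31 genes were higher in HF, 14 were higher in PHF and 9 lay between (median -0.48, or 0.18 by TMM with 13 higher in HF and 9 in PHF, percentile 34.5). CHRDL1, an antagonist of bone morphogenetic proteins, was 134-fold higher in HF. INHBA, the activin and inhibin beta A subunit, was at 986 and 39.3 CPM, 25.1-fold higher in HF. The beta B subunit INHBB went the other way, at 30.5 CPM in HF and 1464 CPM in PHF. INHA, the inhibin alpha subunit, was at 1311 and 1222 CPM, a log2 ratio of 0.10 that was below 0 with 4 settings and -0.37 at a mitochondrial limit of 10%. That limit left 1829 HF and 5096 PHF granulosa-like cells, against 9896 and 9427 in the main setting. The PHF mean of INHA joined unlike cells, at 3574 CPM in PHF clusters 2 and 6 (described below) and 356 CPM in the other PHF cells.

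Genes of WNT signalling and early identity were more often higher in PHF by CPM, as were genes at large. The WNT median lay within the middle 95% of random lists and the identity median just below it. By TMM more identity genes were higher in HF. For WNT signalling, 1 of 16 genes was higher in HF, 10 were higher in PHF and 5 lay between (median -0.84, or -0.17 by TMM with 2 higher in HF and 5 in PHF, percentile 5.97). FZD1, WNT4 and RSPO3 were 10.9-, 9.82- and 9.71-fold higher in PHF. Within HF, WNT4 was at 408 CPM in HF cluster 3 (886 cells, described below) and 17.0 CPM in the other cells. For granulosa identity and early differentiation factors, 5 of 13 genes were higher in HF, 7 were higher in PHF and 1 lay between (median -0.90, or -0.24 by TMM with 6 higher in HF and 5 in PHF, percentile 2.29). WT1, a transcription factor of the early gonad, was at 2.90 CPM in HF and 127 CPM in PHF (44.0-fold), and NR0B1 was 7.62-fold higher in PHF. GATA4 was at 95.2 and 248 CPM. ESR1, an estrogen receptor, was 8.10-fold higher in HF, and NR5A2, a nuclear receptor that drives steroid genes, was at 1225 and 213 CPM. Within PHF, NR5A2 was at 700 CPM in PHF clusters 2 and 6 (described below) and 33.7 CPM in the other cells. FOXL2 was at 15.9 CPM (15.2 to 16.7) and 7.97 CPM (7.37 to 8.61).

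Cell division genes were far higher in PHF. For the S phase list, 0 of 22 genes were higher in HF, 20 were higher in PHF and 2 lay between (median -3.05, percentile 0). RRM2, SLBP and DTL were 24.5-, 20.5- and 14.98-fold higher in PHF. For the G2 and M phase list, 0 of 25 genes were higher in HF, 24 were higher in PHF and 1 lay between (median -4.45, percentile 0). MKI67, a marker of dividing cells, was at 1.28 CPM in HF and 55.8 CPM in PHF, and CCNB3, ANLN and NDC80 were 38.2-, 36.3- and 31.3-fold higher in PHF. With each cell thinned to 3000 UMIs, 192 of 9766 HF cells had at least 3 UMIs of the G2 and M phase list, or 1.97% (1.70% to 2.26%), against 4926 of 9171 PHF cells, or 53.7% (52.7% to 54.7%). Without thinning the shares were 14.3% and 88.3%, and thinning left out 130 HF and 256 PHF cells that were too shallow. Cells 1 UMI below the threshold made up 4.19% of HF and 18.1% of PHF cells. At 5 UMIs the shares were 0.717% and 27.8%. The score is not a phase call, because PHF cells outside the clusters of dividing cells held 3.06 list UMIs per 3000 on average, which is at the threshold. Free RNA of dividing cells was not measured apart.

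The ribosomal protein list was higher in HF and the stress list was higher in PHF by CPM. Of 81 measured genes whose symbols begin as ribosomal proteins do, 64 were higher in HF, 5 were higher in PHF and 12 lay between (median 1.00, percentile 100). RPS15A, RPLP0 and RPL22L1 were 3.21-, 3.20- and 2.96-fold higher in HF. The rule also took in kinases of ribosomal protein S6, and 3 of these were among the 5 genes higher in PHF, with RPS6KA2 at 5.98-fold. Among 13 mitochondrially encoded proteins, 3 were higher in HF, 2 were higher in PHF and 8 lay between (median 0.35, or 1.01 by TMM with 11 higher in HF and 0 in PHF, percentile 74.8). COX3, COX1 and COX2 had log2 ratios of 0.70, 0.63 and 0.63, and ATP8 had -0.81, or -0.15 by TMM. For immediate early and dissociation stress, 0 of 18 genes were higher in HF, 11 were higher in PHF and 7 lay between (median -0.86, percentile 2.10), but by TMM 4 were higher in HF and 6 in PHF. MYC, HSPA2, DUSP1 and IER5 were 6.69-, 5.24-, 4.89- and 3.40-fold higher in PHF. Mitochondrial transcripts made up 12.3% of the HF and 9.41% of the PHF sums.

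The other lists lay near random lists or turned with scaling. For apoptosis, 2 of 19 genes were higher in HF, 7 were higher in PHF and 10 lay between (median -0.44, or 0.23 by TMM over the same genes with 5 higher in HF and 2 in PHF, percentile 74.6). BCL2, which opposes cell death, was 8.75-fold higher in HF, and BID and BOK, which promote it, were 3.24- and 2.64-fold higher in PHF. TNFRSF1A was 1.95-fold higher in PHF. For glycolysis and hypoxia, 6 of 22 genes were higher in HF, 4 were higher in PHF and 12 lay between (median -0.09, or 0.58 by TMM with 11 higher in HF and 1 in PHF, percentile 95.05). HK2 and VEGFA were 4.97- and 2.67-fold higher in HF, and EGLN3 was 17.6-fold higher in PHF. For antioxidant and redox genes the counts were 3, 5 and 7 of 15 (median -0.34, or 0.32 by TMM with 7 higher in HF and 0 in PHF, percentile 48.8). PRDX3, GSTM2 and TXN were 2.59-, 2.26- and 1.93-fold higher in HF, and GPX4 was 2.38-fold higher in PHF. For prostaglandin and angiogenesis genes, 2 of 9 were higher in HF, 6 were higher in PHF and 1 lay between (median -0.67, or 0.00 by TMM with 2 higher in HF and 4 in PHF, percentile 47.6). PTGFR, a prostaglandin receptor, was 230-fold, EDN1 61.3-fold, ANGPT2 19.5-fold and PTGS1 6.86-fold higher in PHF.

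Matrix and junction genes also went both ways. For basement membrane and matrix, 2 of 11 genes were higher in HF, 5 were higher in PHF and 4 lay between (median -0.35, or 0.31 by TMM with 4 higher in HF and 3 in PHF, percentile 53.4). FBN1, AGRN and VCAN were 6.48-, 6.14- and 3.60-fold higher in PHF, and NID2 was 3.50-fold higher in HF. For cell junction and cytoskeleton, 2 of 12 genes were higher in HF, 4 were higher in PHF and 6 lay between (median -0.41, or 0.25 by TMM with 3 higher in HF and 3 in PHF, percentile 41.3). The claudins were opposed: CLDN1 was 109-fold higher in PHF and CLDN5 was 19.1-fold higher in HF. TPM1 was 14.0-fold and the gap junction gene GJA1 2.40-fold higher in PHF.

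**Figure D2:**
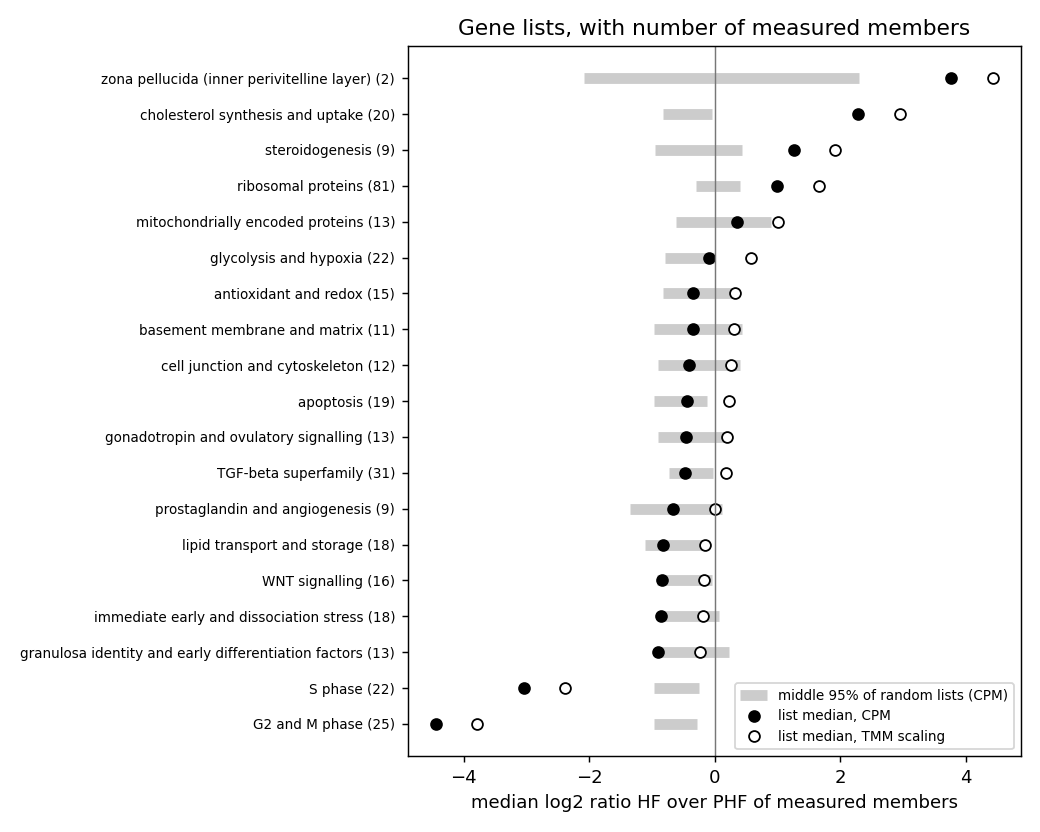
Median log2 ratio of HF over PHF for each gene list, by CPM (filled circles) and by TMM scaling (open circles), with the middle 95% of random lists of the same size and expression by CPM (grey bars) and the number of measured genes in brackets. Cholesterol synthesis and uptake lies at 2.28 and the G2 and M phase list at -4.45 by CPM.

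Shares of cells with a UMI differed widely between the libraries for LHCGR, AMH and FST. With each cell thinned to 3000 UMIs, LHCGR was seen in 77.5% of HF cells (76.6% to 78.3%) and 1.32% of PHF cells (1.10% to 1.57%). AMH was seen in 0.184% and 33.9% of cells, FST in 1.74% and 79.0%, and WT1 in 1.12% and 24.6%. STAR was seen in 63.5% and 15.7%, CYP11A1 in 99.1% and 27.5%, HSD3B1 in 99.5% and 50.2%, and INHBA in 67.0% and 8.42%. INHA was seen in 93.2% of HF but 55.9% of PHF cells, at like mean levels. FSHR was seen in 46.7% and 57.7%, GATA4 in 24.1% and 50.3%, FOXL2 in 4.54% and 2.39%, and ZP3 in 100% and 98.6%. PGR was seen in 2 HF and 8 PHF cells and CYP19A1 in 2 HF and 83 PHF cells. Without thinning, LHCGR was seen in 94.5% and 3.71%, AMH in 0.394% and 52.4%, and INHA in 99.1% and 73.5% of cells. As a gauge of RNA from other cells, chosen after seeing that no other class was present, HBA1 was seen in 0.184% of HF and 0.0763% of PHF thinned cells and CYP17A1 in 0.0717% and 0.142%. The HF share for AMH equals that for HBA1, but HBA1 does not measure free RNA of AMH, so free RNA stays open for it. Of the 50 summed HF UMIs of AMH, 27 lay in 1 cluster of 886 cells (HF cluster 3 below), so they were not spread evenly over the cells. The median number of genes per cell at 3000 UMIs was 1406 in HF and 1712 in PHF.

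**Figure D3:**
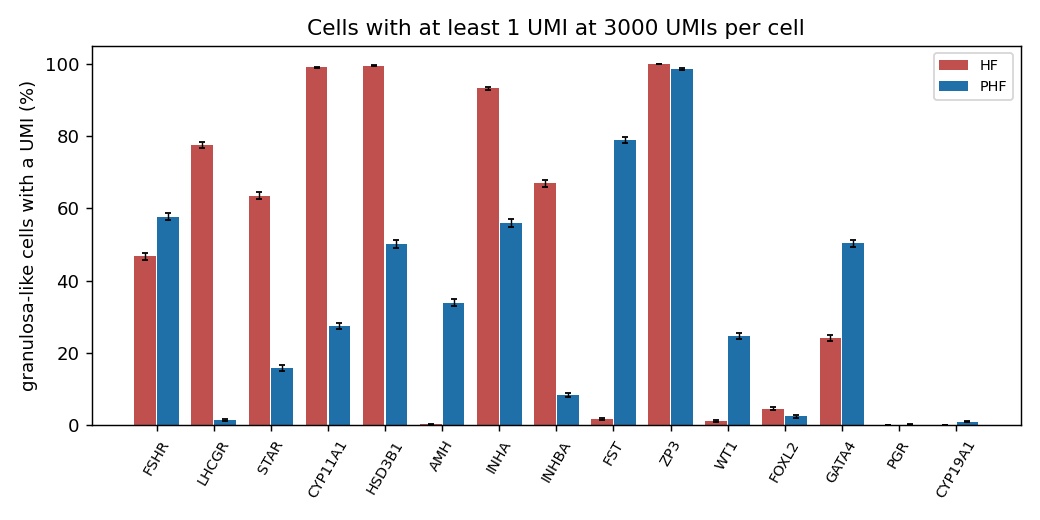
Share of granulosa-like cells with at least 1 UMI of each key gene after thinning to 3000 UMIs per cell, for HF (9766 cells) and PHF (9171 cells); bars start at 0 and error bars are exact 95% binomial intervals for counting error. LHCGR was seen in 77.5% of HF and 1.32% of PHF cells, and FST in 1.74% and 79.0%.

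Within the HF library, granulosa-like cells clustered alone formed 8 clusters. These are descriptions of 1 library, and the genes that lead a cluster also helped define it. HF clusters 1 (3430 cells) and 2 (3380 cells) were the largest. Cluster 1 was led by ST6GALNAC3, CNKSR2, TSPAN7, PIK3R1 and RFX3, and cluster 2 by KCNC2, ADAMTS3, PCP4, INHBA and FGFRL1. INHBA was at 178 CPM in cluster 1 and 1624 CPM in cluster 2, and STAR at 236 and 676 CPM. HF cluster 3 (886 cells) was led by WNT4, IGF2, INHBB, IHH and ADAMTS9, with LHCGR at 170 CPM, INHA at 2396 CPM and ZP3 at 14918 CPM. HF cluster 4 (844 cells; CCN2, THSD7A, AHR1A, HS3ST5 and CLVS2) had INHBA at 2275 CPM. HF cluster 5 (565 cells; ABCC4, PDE3A, ADAMTSL3, PRKG1 and ID1) had INHA at 645 CPM. HF cluster 6 (472 cells; FAM132A, GULP1, CHRM3, CARTPT and NCAM2) had STAR at 1468 CPM and INHA at 2739 CPM. HF cluster 7 (251 cells) was led by the heat shock and early response genes HSPA2, HSPB9, CREB5, NR4A3 and EGR1. HF cluster 8 (68 cells) was led by CEL, SMAD7, INHBB, TSKU and CTHRC1, with FSHR at 974 CPM, LHCGR at 52.1 CPM and INHA at 4533 CPM.

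Within the PHF library, granulosa-like cells formed 12 clusters that were unlike in AMH, INHA and steroid genes. PHF clusters 2 (1323 cells; FABP4, TMEM72, FABP5, NPC2 and SLC5A5) and 6 (760 cells; C11orf96, MAP2, AGBL1, EMP1 and CEL) had INHA at 4139 and 2490 CPM, CYP11A1 at 463 and 511 CPM, STAR at 258 and 313 CPM, and AMH at 17.1 and 14.8 CPM. PHF cluster 1 (1719 cells; TH, PLAC8L1, IGSF11, NPAS3 and SLITRK4) had INHA at 288 CPM, CYP11A1 at 30.4 CPM and AMH at 294 CPM. PHF cluster 3 (1088 cells) was led by CDH11, ADGRL3, PLPPR1, TMSB15B and ZCCHC24, and PHF cluster 4 (1068 cells) by GPR149, RALYL, HOXA9, CCNO and HSD17B1. AMH was at 191 and 385 CPM in these. PHF clusters 5 (978 cells; DRGX, PLPPR1, KCNK2, WT1 and WNT16) and 11 (310 cells; DGKB, WT1, IL1RAPL1, SNTG1 and MAGI2) had FST at 1965 and 1688 CPM. PHF cluster 7 (613 cells; CCNB3, KPNA2, KIF20A, NEK2 and NUSAP1) and PHF cluster 12 (184 cells; CDK1, SMC2, CDCA3, UBE2U and MKI67) were led by genes of division. Cluster 7 had INHA at 193 CPM and AMH at 447 CPM, and cluster 12 had INHA at 3048 CPM and AMH at 21.1 CPM. PHF cluster 8 (581 cells) was led by NYX, FOS, CYR61, SCD and IER5, and PHF cluster 9 (418 cells) by ID1, INPP4B, MCTP1, ABCC4 and ZBTB7C. PHF cluster 10 (385 cells) was led by F3, PTGS2, HBEGF, PLAU and PTGFR, with FST at 2130 CPM, AMH at 626 CPM and INHA at 83.9 CPM. LHCGR was between 2.13 and 7.13 CPM in the 12 PHF clusters, and PGR and CYP19A1 stayed under 10 CPM in all clusters of both libraries.

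**Figure D4:**
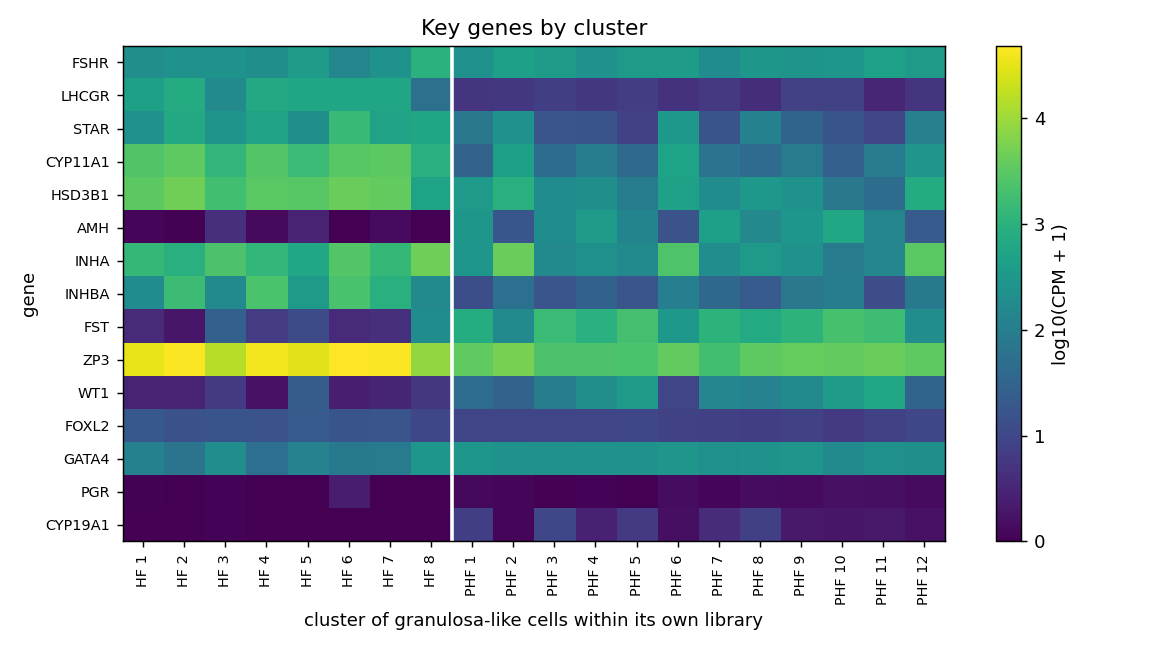
Level of each key gene, as log10 of CPM plus 1, in the 8 HF and 12 PHF clusters of granulosa-like cells, each clustered within its own library (white line between libraries). INHA is at 4139 CPM in PHF cluster 2 and 288 CPM in PHF cluster 1, and AMH at 17.1 and 294 CPM.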

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

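The basis for leading genes and the ribosomal list without S6 kinases were chosen after seeing the data; the other alternatives were not. Among gene counts, lists and cell shares, 233 values under an alternative stayed within the stated spread or 1.5 times the main count, 51 moved and 3 reversed, where reversed means that a median whose resampling interval excludes 0 changed sign. Other medians also crossed 0, as given below, and the cause was not tested where none is named. Median of ratios and TMM scaling add 0.66 and 0.67 to every log2 ratio, which by construction moved the counts and most lists. Genes at least 2-fold higher in HF went from 411 to 897 and 902, and those higher in PHF from 1139 to 400 and 400. With a lower filter more genes enter: 2005 were higher in PHF at 20 CPM, and 1533 in HF and 6617 in PHF with only 10 UMIs.

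Here list members were filtered anew under each scaling, so some medians differ by another amount than the shift and from those over fixed members. List medians under median of ratios and TMM were 2.94 and 2.95 for cholesterol, 4.43 and 4.43 for zona pellucida, 1.66 and 1.66 for ribosomal proteins, and 1.01 and 1.01 for mitochondrial proteins. They were -0.17 and -0.17 for WNT signalling, -0.20 and -0.19 for stress, and -3.60 and -3.59 for G2 and M phase. They lay on the other side of 0 for the TGF-beta superfamily (0.18 and 0.18), basement membrane (0.31 and 0.31), cell junction (0.25 and 0.25), glycolysis (0.58 and 0.58), gonadotropin signalling (0.20 and 0.20), redox genes (0.32 and 0.32), prostaglandin genes (0.00131 and 0.00571) and apoptosis (0.32 and 0.32). Apoptosis at 50 CPM (0.067) and glycolysis at 50 CPM (0.14) also lay above 0. G2 and M phase was -3.74 at 10% mitochondrial UMIs, stress -1.35 and ribosomal proteins 0.87 over all kept cells, and ribosomal proteins 1.05 with the mean over cells.

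The granulosa-like share of HF was 96.9% at 10% mitochondrial UMIs, 90.2% with no limit, 88.5% with 1000 genes, 84.0% with doublets kept and 94.1% with leading genes against both libraries. That of PHF was 80.1% at 10% mitochondrial UMIs, 75.1% with 1000 genes, 78.4% at resolution 1.2 and 65.5% with leading genes against both libraries. The share of HF cells at or over the G2 and M phase threshold, which is no share of dividing cells, was 2.68% at 10% mitochondrial UMIs, 0.823% at 1500 UMIs and 0.717% at a threshold of 5. That of PHF was 50.5%, 27.2% and 27.8% under these settings, 52.0% with 1000 genes, 52.1% at resolution 1.2 and 52.4% with leading genes against both libraries. Of the 99 named genes, only FSHR (under both scalings) and INHA (4 settings) changed sign. Besides scaling, ratios moved over 1.5-fold for 17 genes at 10% mitochondrial UMIs, 6 over all kept cells, 3 with the mean over cells, 1 with doublets kept and 1 at resolution 0.4. The limit of 10% left 1829 HF and 5096 PHF granulosa-like cells, against 9896 and 9427 in the main setting. The largest of these shifts were 2.06 (SYBU, all kept cells) and 1.81 (PGR, doublets kept). All 15 key genes kept the order of the libraries in shares at 1500 UMIs, though PGR rests on very few cells. No paired analysis was possible because each group has 1 library. Depth limits PGR and CYP19A1, with under 300 UMIs each.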

Other observations

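Tests of doublets, of the library in its average makeup and of a single cluster as source were chosen after the values were seen; the other tests were not. For the average makeup tests the quartiles were also added to the rule after the result was seen; by the median alone, the rule first written, both would count against that source. One gene without a symbol, LOC422926, a protein-coding gene on chromosome 4 (85557576 to 85566789), was singled out after its values were seen. It was at 22082 CPM in PHF and 5.81 CPM in HF granulosa-like cells, 3801-fold higher in PHF. Within PHF it was at 1310, 1291 and 1617 CPM in clusters 2, 6 and 12 and between 21180 and 44784 CPM in the other 9.

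The clusters left without a name also held granulosa genes. PHF cluster 10 of the joint clustering (604 cells) was led by POSTN (1891 CPM) and TWIST1 (1042 CPM), with FSHR at 389 CPM, FST at 512 CPM and CDH2 at 973 CPM. PDGFRB was at 27.6, PDGFRA at 8.80, COL1A1 at 1.06, DCN at 2.11 and LUM at 0.704 CPM. Its ZP3 (813 CPM) and GATA4 (47.4 CPM) were below those of every other PHF cluster, INHA was at 81.2 CPM, CYP11A1 at 21.5 CPM and COL1A2 at 112 CPM. HF clusters 5 (669 cells) and 8 (557 cells) had COL1A2 at 375 and 203 CPM, with CYP11A1 at 2533 and 1798 CPM. PHF cluster 17 (406 cells) had MYH11 at 224 CPM and AMH at 430 CPM.

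HF cluster 3 of the clustering within the library (886 cells) carried genes that were otherwise higher in PHF. HF cluster 8 (68 cells), not tested as a pattern, held some of them at higher levels (WNT4 1775, INHBB 2203 and SMAD7 571 CPM) and LOC422926 at a lower level (11.3 against 61.3 CPM). In cluster 3 WNT4 was at 408 CPM against 17.0 CPM in the other HF cells, and list UMIs of G2 and M phase were at 781 CPM against 101 CPM in HF cluster 1. Doublets are argued against by a median of 8650 UMIs against 10607 in the other cells and a median doublet score of 0.101 against 0.168. PHF cells or their RNA stay open as part of a mixture: of 23 genes at least 5-fold higher in cluster 3, 0% lay above every PHF cluster. A low share was likely beforehand for cells noted for genes high in PHF, so this alone does not decide. Free RNA spread evenly over HF barcodes would not raise these genes in 1 cluster. WNT4 was at 9.97 and 7.63 CPM in HF clusters 1 and 2. PHF cells without HF RNA would not give cluster 3 its LHCGR (170 CPM) and ZP3 (14918 CPM). These were at 4.63 and 5351 CPM in PHF cluster 2. For PHF in its average makeup, the median share of the PHF excess over 85 high PHF genes was 20.1% (quartiles 9.46% and 36.5%), against 48.8% over the 23 genes, which did not decide; LOC422926, at 61.3 CPM against 22082 CPM in PHF, goes against it. PHF cluster 2 as the single source fitted, the closest of the PHF clusters tried. Its high genes reached a median of 32.6% of its excess (quartiles 22.4% and 43.8%), against 43.0% over the 23 genes. A fit asked only that the lower quartile reach 50% of this last value. The upper quartile was at 102% of that value, but the median and the lower quartile lay below 43.0%. LOC422926 reached 4.58% of the excess of PHF cluster 2; whether that gene's level there is free RNA was not tested.

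PHF clusters 2 and 6 (2083 cells) had INHA at 3574 CPM against 356 CPM in the other 7344 cells, and NR5A2 at 700 against 33.7 CPM. Doublets stay open for these cells. The median doublet score was lower, at 0.0502 against 0.101, but the median UMI count was higher, at 10205 against 7706.5. The score alone had been taken to count against doublets here, while for the HF pattern above the UMI count was lower too. Scores of both patterns are of cells kept after called doublets were removed. HF RNA in its average makeup is argued against. Over 59 genes high in HF these cells reached a median of 5.40% of the HF excess (quartiles 0.407% and 19.3%). Over the 26 of their own 38 leading genes that were higher in HF, the median was 76.0%. Cells or RNA of a single HF cluster stay open. Of the 38 genes, 5 (13.2%) lay above the other PHF cells and every HF cluster, which a mixture of these would not give for those genes. This share was between the bounds set for the test. HF cluster 8 as the source fitted, the closest of the HF clusters tried. Its high genes reached a median of 46.2% of its excess (quartiles 40.5% and 59.6%), against 66.0% over the pattern's genes. A fit asked only that the lower quartile reach 50% of this last value. The upper quartile was at 90.3% of that value, so the median and both quartiles lay below 66.0%. Such a match cannot tell which library was the source, because HF cluster 8 was itself near PHF in some values. Its ribosomal protein list was at 50795 CPM, against 54347 and 51747 CPM in PHF clusters 2 and 6. In the other HF clusters that list was at 91521 CPM or more. ZP3 in HF cluster 8, at 8516 CPM, lay above PHF cluster 2 at 5351 CPM. LHCGR goes against HF cluster 8 as the source, at 4.63 and 3.91 CPM in PHF clusters 2 and 6 and 52.1 CPM in HF cluster 8. Whether that level in HF cluster 8 is free RNA of other HF cells was not tested.

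PHF cells outside the 2 dividing clusters (797 cells, 8.45%) still held 1018 CPM of the G2 and M phase list, against 9542 CPM inside. Free RNA of dividing cells as the single source is argued against: over 26 genes the ratio of the level outside to that inside had a 90th percentile 6.11 times the 10th, where 1 source gives 1 ratio. The 5 genes with most list UMIs outside (CENPE, BIRC5, NUF2, TOP2A and CENPF) held 65.2% of them, and 41.6% inside. They were picked by those UMIs, and TOP2A and CENPF held a smaller share outside than inside, so this does not show use of these genes outside division, and the source of these UMIs stays open.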
